A study of Caenorhabditis elegans with 4 samples.

How the data were processed

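Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map DPY-28 in wild-type N2 Caenorhabditis elegans embryos of mixed stages and both sexes, for which the labels give 20 °C. DPY-28 is a condensin subunit that belongs both to condensin I, which acts on all chromosomes, and to the condensin of the dosage compensation complex, which acts on the X chromosomes of hermaphrodites. Per the labels' protocols, live embryos were fixed in 2% formaldehyde for 30 min, chromatin was sonicated, and 2 mg of extract with 1% sarkosyl was used per immunoprecipitation, of which 10% was kept as input. The antibody was an affinity-purified rabbit polyclonal antibody against DPY-28. The labels give 4 samples, 2 of immunoprecipitated DNA and 2 of input DNA, each numbered as replicate 1 and 2. The labels do not say whether the replicates came from separate cultures, so differences between them measure only the spread between these samples, which may be technical.

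The deposited values used here were the positions and scores of peaks in peak lists. Per the submitters' processing notes, reads were aligned with BWA and the build was ce10; per the file headers, the coordinates are those of WormBase WS220. Each of the ChIP samples has a list that names MACS as its source, and a list for the whole series names MACS v2. The score of each peak is the peak caller's own value as the authors deposited it, and its scale is not named in the files. The lowest scores were 1.30 in the whole-series list, 50.01 in the replicate 1 list and 50.05 in the replicate 2 list, so the whole-series scores are on another scale than those of the replicate lists. Whether the replicate lists share a scale is not stated in the files, and scores were compared only within a list. Scores of 3100 were shared by 22 peaks of replicate 1 and 65 peaks of replicate 2, so the order among the highest peaks of these lists is partly tied. Caller versions, thresholds, read numbers, and how replicates and input entered the whole-series list are not given in the sources used here. The read depth is therefore unknown, and no read-level error can be given for a peak. No peak list of the input samples was used here, and no background measured in input stands beside the values.

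From these lists, peaks were counted, their covered length was taken as the union of their intervals, and each peak was placed by its midpoint. The size of each chromosome was taken as the last peak end in any of the 3 lists. Mitochondrial peaks were kept out of all comparisons between chromosomes. X and autosomes were compared by a two-sided permutation test on 500-kb bins with 100000 resamples, for which the smallest p is 1e-05; bins rather than peaks were permuted because neighbouring peaks are not independent. A last bin shorter than 50% of this size was joined to its neighbour. Intervals of the X to autosome ratio are 95% percentile intervals from 10000 resamplings of bins. With 1 X and 5 autosomes, an exact test over whole chromosomes could not go below p = 0.167. Scores and widths were compared within a list by the difference of medians with a two-sided permutation test of 100000 resamples over peaks, which are not independent replicates. Peaks of 2 lists were called shared when they overlapped by at least 1 bp, and 1000 circular shifts of a list within each chromosome (a circular permutation test) gave the chance level, with a smallest two-sided p of 0.002. Shared shares on X and autosomes were compared with Fisher's exact test, two-sided, which takes peaks as independent although neighbouring peaks are not. Spearman correlations of scores across shared peaks have permutation p-values, and peaks are again not independent. Chromosome arms were the outer parts of each chromosome and centres the middle 33.3% of its length, compared over 500-kb bins by permutation with Benjamini-Hochberg adjustment over the 6 chromosomes. Spacing between neighbouring midpoints was compared with 1000 uniform placements of as many peaks per chromosome. Intervals of shares are exact (Clopper-Pearson) 95% intervals, and they cover counting error only. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

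The procedures were tested on simulated peak lists. For 1763 autosomal peaks and no difference in density, 4% of 100 simulated lists passed p = 0.05 in the permutation test of bins; with a true ratio of 2, the mean recovered ratio was 2.00 and 100% passed. For lists built with 40% of peaks in common, the mean shared share was 41.4%, and for unrelated lists 2% of 100 pairs passed. The simulated peaks had a fixed width and were placed uniformly and independently, and the tests on them used fewer permutations and shifts. These rates therefore do not show how the tests behave where neighbouring peaks are not independent.

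Regions named in the text are, for X and for autosomes, the 10 highest scoring peaks of the whole-series list that overlap a peak in both replicate lists. This rule, the tests, and the alternatives were set before the data were examined, with exceptions. The test of widths, the test of the arm to centre difference between the replicate lists, the bootstrap intervals and the comparison of scores between shared and unshared peaks were added afterwards, as were the choices so named in the closing section. The alternatives were other bin sizes, stricter score limits, each replicate list alone, peaks found in both replicate lists, merging of peaks closer than 500 bp, leaving out each autosome, other overlap rules and another definition of the chromosome centre. Gene positions, gene classes, motif content and GC content of peaks were planned but not analysed here: the gene table at hand is of assembly WBcel235, not of the build of the peak lists, and no genome sequence was used here. That table served only for gene order and, in an alternative, for chromosome size.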

Results

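DPY-28 binding was measured by ChIP-seq in mixed-stage wild-type embryos, in 2 ChIP samples and 2 input samples. The data consisted of 3 peak lists. The whole-series list held 10867 peaks, the list of ChIP replicate 1 held 3274 and that of ChIP replicate 2 held 5244. Of these, 6, 1 and 0 peaks respectively lay on mitochondrial DNA and were left out of the comparisons between chromosomes. The nuclear peaks covered 4.12 Mb in the whole-series list, 1.60 Mb in replicate 1 and 3.83 Mb in replicate 2. Their median widths were 287 bp, 373 bp and 582 bp. The p-values of the bin and peak tests measure the spread along the genome within a list; the spread between samples rests on n = 2 ChIP samples.

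The first comparison asked how DPY-28 peaks were divided between X, the target of dosage compensation in C. elegans, and the autosomes. X held 9098 of the 10861 nuclear peaks of the whole-series list, or 83.8% (exact 95% interval 83.1 to 84.5%), and the 5 autosomes together held 1763. The density was 513 peaks per Mb on X and 21.4 peaks per Mb on autosomes, a ratio of 24.0 (95% interval 22.3 to 25.98). Autosomes were close to each other, from 18.5 peaks per Mb on V and 20.9 on II to 22.3 on III, 22.7 on I and 23.3 on IV. Peaks covered 19.7% of X (3486 kb) and 0.77% of the autosomes (635 kb), a ratio of 25.6 (95% interval 22.8 to 29.0). Each of the 35 X bins of 500 kb held more peaks per Mb than any of the 166 autosomal bins: the X bins ranged from 336 to 592 peaks per Mb and the autosomal bins from 4 to 58. The difference between X and autosomal bins had p = 1e-05 in the two-sided permutation test, the smallest p it can give, for both peak number and covered length. In the highest scoring 10% of the list the ratio was 89.04 for peak number and 58.6 for covered length.

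**Figure D1:**
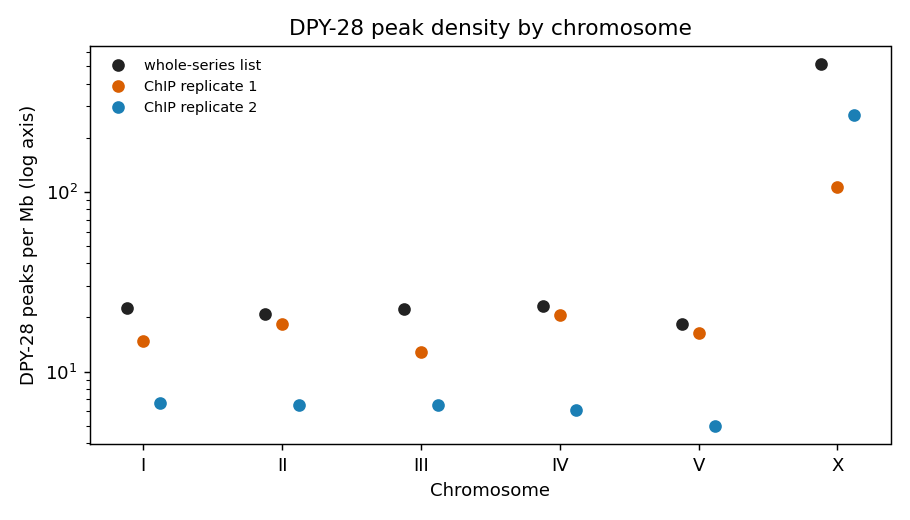
DPY-28 peaks per Mb (log axis) on each nuclear chromosome, 1 point per peak list. In each list X lies above every autosome: 513, 107 and 268 peaks per Mb on X in the whole-series list, replicate 1 and replicate 2.

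Both ChIP samples had the excess on X, to different degrees. In replicate 2, X held 4743 of 5244 peaks, or 90.4% (exact 95% interval 89.6 to 91.2%). In replicate 1, X held 1889 of 3273 nuclear peaks, or 57.7% (56.0 to 59.4%). The mean X share was 74.1% ± 23.1 (SD, n = 2). The ratio of X to autosomal density was 44.1 (95% interval 39.5 to 50.2) in replicate 2 and 6.36 (5.70 to 7.06) in replicate 1, with a mean of 25.2 ± 26.7 (SD, n = 2). On X, replicate 2 had 268 peaks per Mb and replicate 1 had 107; on autosomes the order was the opposite, with 6.07 peaks per Mb in replicate 2 and 16.8 in replicate 1. All 35 X bins exceeded every autosomal bin in peak number in both replicate lists (p = 1e-05 in each, permutation test). In covered length the ratio was 38.7 (32.8 to 47.5) in replicate 2 and 5.00 (4.25 to 5.90) in replicate 1, where 7 of the 35 X bins exceeded every autosomal bin. The size of the X excess thus depended strongly on the sample, while its direction was shared by both.

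**Figure D2:**
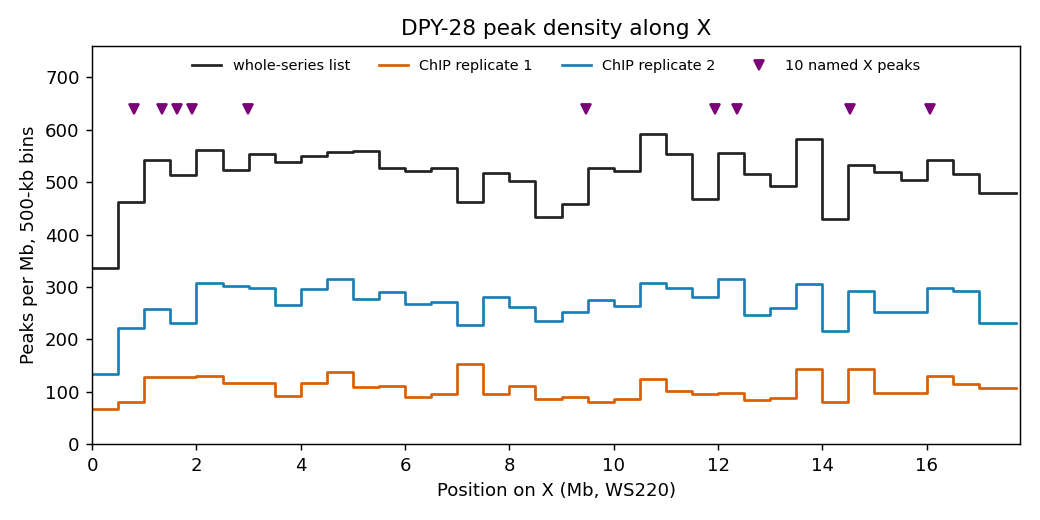
DPY-28 peaks per Mb along X in 500-kb bins (WS220 positions), 1 line per peak list, with triangles at the midpoints of the 10 named X peaks. Peaks were spread along the whole chromosome, with the lowest bin at the left end in all 3 lists (336, 68 and 134 peaks per Mb in the whole-series list, replicate 1 and replicate 2).

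Along X, peaks were spread over the whole chromosome. The bin density in the whole-series list averaged 514 ± 49.8 peaks per Mb (SD over 35 bins). The arms of X had 517 peaks per Mb and its centre 507, a ratio of 1.02 (permutation p = 0.60, adjusted p = 0.72). The median distance between neighbouring X peaks was 1.41 kb, against 1.35 kb for uniform random placement (1.32 to 1.38 kb in 95% of placements). The replicate lists did not share this direction. The distance was 2.53 kb in replicate 2, within the 2.52 to 2.67 kb of random placement, and 5.58 kb in replicate 1, below the 6.22 to 6.80 kb of random placement. Uniform placement sets no minimum distance between peaks, while called peaks have widths and covered 19.7% of X in the whole-series list. A distance above random placement, as in that list, can therefore come from the comparison itself. On autosomes, neighbouring peaks were 25 kb apart in the whole-series list, closer than in random placement (30.6 to 33.9 kb). This closer spacing was present in replicate 1 (27.8 kb against 38.2 to 42.9 kb) and not in replicate 2 (115 kb against 103 to 123 kb). After peaks closer than 500 bp were merged, the ratio to random placement in the whole-series list was 0.94, against 0.77 as deposited. Merging takes the shortest distances out of the list and not out of random placement, so a rise of this ratio is built in.

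The strongest peaks of the whole-series list were on X. The 100 highest scoring peaks were all X peaks (exact 95% interval of the X share 96.4 to 100%), and 523 X peaks, 5.75% of those on X, scored above the highest autosomal peak. In the replicate lists, where many of the highest scores are tied at 3100, 1 X peak of replicate 1 and 3 X peaks of replicate 2 did so. The X share was 90.9% (89.6 to 92.1%) in the highest scoring 20% of the list and between 81.0% and 82.4% in the other slices of that size. In replicate 2 the X share went from 95.9% (94.5 to 97.0%) in the highest 20% to 85.2% (82.9 to 87.3%) in the lowest. In replicate 1 it was 59.4% (55.5 to 63.2%) in the highest 20% and 52.8% (48.8 to 56.6%) in the lowest, and 47 of the 100 highest scoring peaks lay on X. The median score was 6.91 on X and 6.24 on autosomes in the whole-series list, a difference of 0.67 (permutation p = 3e-05). In replicate 2 the medians were 169 and 113 (permutation p = 2e-05), and in replicate 1 they were 106 and 103, a difference that did not pass the test (p = 0.35). The mean of 500-kb bin medians was 0.12 higher on X than on autosomes in the whole-series list (permutation p = 0.81). This is another measure than the difference of 0.67, because each bin weighs alike however few peaks it holds. For scores divided by width the difference of medians was 0.85 per kb, on another scale, and did not pass the test (permutation p = 0.091). Among the upper 50% of peaks by score it was 2.895 (permutation p = 1e-05). X peaks were also wider than autosomal peaks, with medians of 298 bp and 244 bp in the whole-series list (permutation p = 1e-05), 384 bp and 349 bp in replicate 1 (p = 0.0023) and 588 bp and 513 bp in replicate 2 (p = 2e-05).

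**Figure D3:**
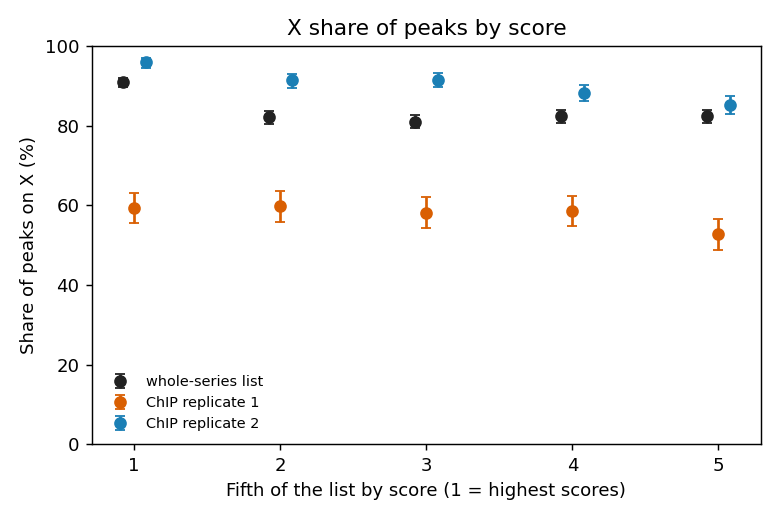
Share of nuclear peaks on X (percent) in each slice of 20% of a list ranked by score, from the highest (1) to the lowest (5); bars are exact 95% intervals. In the whole-series list the share is 90.9% in the highest slice and between 81.0% and 82.4% in the others. It goes from 95.9% in the highest to 85.2% in the lowest slice of replicate 2, and lies between 52.8% and 59.7% in replicate 1.

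Among peaks found in both replicates, the highest scoring X region was X 2995592 to 2997864 (WS220; 2273 bp, score 261). It was followed by X 805312 to 808024 and X 9463276 to 9469295, both with a score of 260.97. The regions X 1342621 to 1346297 and X 16055087 to 16057657 each scored 259.72, and X 11935378 to 11939145 scored 257.67. The remaining named X regions were X 14522946 to 14529069 (score 251.48), X 1626220 to 1627786 (249.77), X 1908624 to 1909989 (248.51) and X 12361451 to 12364236 (245.84). All 10 overlapped a replicate 2 peak with the score of 3100 shared by 65 peaks of that list. In replicate 1 their scores ran from 102.42 for X 1626220 to 1627786 to 3100 for X 11935378 to 11939145. The widths of the 10 regions ran from 1366 to 6124 bp.

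The highest scoring autosomal region found in both replicates was III 10461038 to 10461396 (359 bp), with a score of 56.85. It was followed by IV 14032550 to 14034434 (score 55.03), III 6133281 to 6133676 (51.15), V 13868750 to 13869167 (49.74) and V 11313998 to 11314495 (48.17). The other named autosomal regions were IV 11325929 to 11326410 (46.42), II 11960622 to 11960895 (44.81), V 19642996 to 19643292 (44.35), I 10130491 to 10133129 (43.99) and V 17125131 to 17125933 (41.25). Of these, I 10130491 to 10133129 had a score of 3100 in replicate 2 and 284 in replicate 1, and V 13868750 to 13869167 had 167 in replicate 2 and 1542.5 in replicate 1. The first region, on III, scored 131 in replicate 1, rank 542 among its autosomal peaks. Replicate 1 scores of the 10 ran from 53.79 (II), near that list's lowest of 50.01, to 3100 (V 17125131 to 17125933). The latter overlapped wider peaks, V 17119789 to 17126674 in replicate 1 and V 17119860 to 17127588 in replicate 2. Which genes lie at these regions was not analysed here.

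The next comparison asked how far both ChIP samples found the same regions. On X, 89.2% of the replicate 1 peaks (1685 of 1889) overlapped a replicate 2 peak, against 29.4% for circular shifts (27.3 to 31.6%). In the other direction, 30.2% of the 4743 X peaks of replicate 2 overlapped a replicate 1 peak, against 11.3% by chance. On autosomes, 16.5% of the replicate 1 peaks (229 of 1384) overlapped a replicate 2 peak, against a chance level of 0.80% (0.36 to 1.37%), and 43.9% of the 501 autosomal peaks of replicate 2 were found in replicate 1, against 2.07% by chance. Each of these shares exceeded all 1000 shifts (circular permutation p = 0.002, the smallest they can give). The share of replicate 1 peaks that were found again was 72.7 percentage points higher on X than on autosomes (odds ratio 41.7, log10 of Fisher's exact p = -415). For replicate 2 peaks it was lower on X than on autosomes by 13.7 percentage points (odds ratio 0.55, Fisher's exact p = 1e-09). When each peak of a pair had to cover 50% of the other, 23.0% of all replicate 1 peaks were found in replicate 2 and 14.4% of all replicate 2 peaks in replicate 1, against 58.5% and 31.5% with 1 bp, and the difference of 72.7 points became 20.1 points (Fisher's exact p = 6.9e-44). Fisher's exact test takes peaks as independent, which neighbouring peaks of 1 sample are not. The 1685 shared X peaks of replicate 1 overlapped only 1433 X peaks of replicate 2. The Fisher p-values therefore do not measure how certain these differences are. Because chance overlap also differed between X and autosomes, these differences do not by themselves compare reproducibility.

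**Figure D4:**
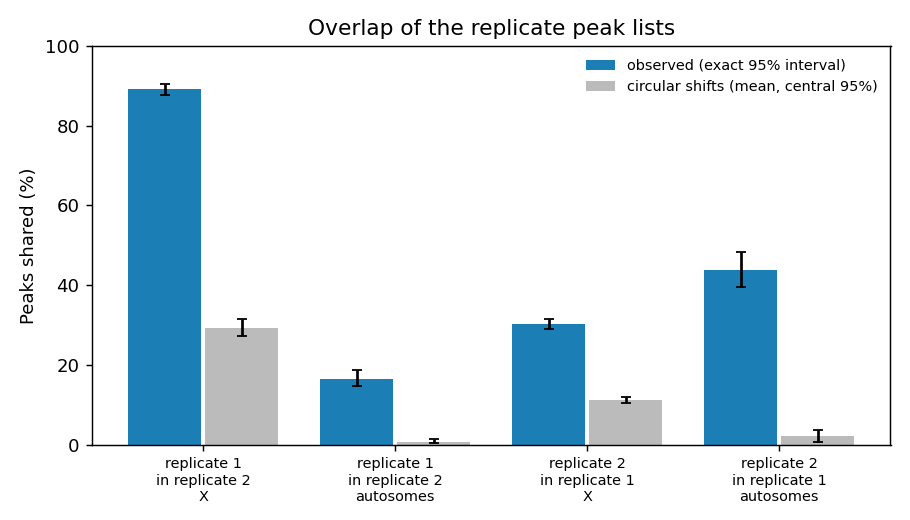
Share of peaks of a replicate list (percent) that overlap a peak of the other list by at least 1 bp, for X and autosomes; blue bars are observed with exact 95% intervals, grey bars are the mean of 1000 circular shifts with their central 95%. Each observed share exceeds its chance level, with the highest (89.2%) for X peaks of replicate 1 and the lowest (16.5%) for autosomal peaks of replicate 1.

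Peaks found in both samples scored higher. On X, replicate 2 peaks that overlapped a replicate 1 peak had a median score of 596, and those that did not had 124. On autosomes, the corresponding medians of replicate 2 were 172 and 87.6, and those of replicate 1 were 142 and 99.5. Shared peaks were also wider, with median widths in replicate 2 of 823 against 507 bp on X and 658.5 against 453 bp on autosomes. In replicate 1 these widths were 391 against 327.5 bp on X and 432 against 333 bp on autosomes. Wider peaks overlap more often by chance under the 1 bp rule, and score was not separated from width. Each replicate 1 peak was paired with the highest scoring replicate 2 peak it overlapped, so a replicate 2 peak could serve more than once. Across the 1914 replicate 1 peaks with a partner, the Spearman rho of scores was 0.49 (permutation p = 1e-05). It was 0.56 across the 1685 on X and 0.54 across the 229 on autosomes (permutation p = 1e-05 for each). With 50% reciprocal overlap, rho was 0.65 (permutation p = 1e-05).

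The whole-series list contained almost all replicate 2 peaks (98.6%, against 42.7% for circular shifts) and 78.8% of the replicate 1 peaks (against 22.7%). The replicate 1 peaks it contained were 97.1% of those on X and 53.8% of those on autosomes. Of the whole-series peaks, 16.5% (1789) were found in both replicate lists, 38.6% in replicate 2 only, 7.44% in replicate 1 only and 37.5% (4070) in neither. The whole-series list has another caller label and score scale, and how it was made is not stated. These shares therefore do not measure how far the samples reproduced each other. The median score was 28.8 for peaks found in both, 8.96 and 5.84 for those in replicate 2 only and replicate 1 only, and 4.36 for those in neither. The X share was 86.1% among peaks found in both and 85.7% among peaks found in neither, and it was 92.9% for replicate 2 only and 21.7% for replicate 1 only.

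The last comparison set the arms of the autosomes against their centres, which differ in gene density and recombination. In the whole-series list, autosomal arms had 21.2 peaks per Mb and centres 21.7, a ratio of 0.98 (permutation p = 0.77). No chromosome passed after adjustment; the lowest ratio was 0.69 on III (permutation p = 0.046, adjusted p = 0.28). The replicate lists had opposite directions. In replicate 1, arms had 18.6 peaks per Mb and centres 13.2, a ratio of 1.41 (permutation p = 0.00048), with ratios of 1.91 on I and 2.07 on II that passed adjustment (adjusted p = 0.021 for each). In replicate 2, arms had 5.37 peaks per Mb and centres 7.44, a ratio of 0.72 (permutation p = 0.0046), and no single chromosome passed (V, the lowest, had a ratio of 0.59 and an adjusted p of 0.23). A permutation of arm and centre bins on the difference between the lists, chosen after both directions had been seen, gave p = 1e-05. Bins are not replicates and each list comes from 1 sample, so this p compares these 2 lists only and does not measure the spread between samples.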

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

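The tests of the X share by score and of calls particular to replicate 1, and the reading of mitochondrial peaks, were chosen after the results were seen; the test of wide regions and that of repeats and chromosome ends were set before their results were seen.

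Mitochondrial DNA, which lies outside the comparisons of the report, carried 6 peaks in the whole-series list, a signal in data that no comparison used. They lay between positions 4570 and 12646 with scores of 6.65 to 31.64. Replicate 1 had 1 mitochondrial peak, at 12328 to 12748 with a score of 102.92, and replicate 2 had 0. Whether reads from the many copies of mitochondrial DNA piled up in 1 library was left undecided, because 1 peak against 0 is too few. No biological explanation was tested.

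The 2 ChIP samples carry the same labels and differed in X share, 57.7% against 90.4%. Weak autosomal calls near the score limit are argued against as the whole cause: the highest scoring 10% of replicate 1 had an X share of 57.5% (exact 95% interval 51.9 to 62.9%), below the midpoint of 74.1% between the 2 lists. Wide regions cut into calls less than 500 bp apart are argued against as the whole cause. After merging peaks closer than 500 bp and leaving out those over 2 kb, the share was 58.8% (56.9 to 60.6%). This left 1119 autosomal replicate 1 peaks of 1384. Pieces farther apart were not joined, so cuts with longer gaps stay open. Of the autosomal peaks, 53.8% of replicate 1 and 93.6% of replicate 2 were found in the whole-series list, but that list holds 98.6% of replicate 2 and how it was made is not stated, so these shares leave open whether autosomal calls particular to replicate 1 made the gap. The 633 autosomal replicate 1 peaks found in neither other list were 2.00 times as dense on arms as in centres (permutation p = 3e-05), with a median score of 75.2. The 229 found in replicate 2 had an arm to centre ratio of 0.70 (permutation p = 0.09) and a median score of 142. No biological explanation was tested.

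Autosomal peaks shared by both replicates exceeded chance by 20.8 times for replicate 1 peaks. If peaks over 2 kb or within 10 kb of chromosome ends, where reads from repeats can pile up, made the whole excess, it should end without them. Without them, 195 of 1334 autosomal replicate 1 peaks, 14.6% (12.8 to 16.6%), were still shared, against 0.57% by chance (upper bound of the shifts 1.05%). The filter left 1334 of 1384 autosomal peaks in replicate 1 and 461 of 501 in replicate 2. Having removed so few, it could hardly end an excess that rested on 229 shared peaks, and it does not weigh repeats in general as a cause. Narrow repeats away from the ends, open chromatin that gives signal with any antibody, and condensin I on autosomes stay open as untested explanations.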

How the results depend on the processing

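The X excess kept its direction and permutation p of 1e-05 under all 15 alternatives each for density and covered length. Bin size could not change whole-chromosome ratios. Leaving out an autosome could not change direction or p, as all X bins exceeded all autosomal bins. Outside the replicate lists, the density ratio was 20.99 to 89.04 and the covered-length ratio 24.3 to 58.6, highest in the top 10% by score. Single replicate lists gave 6.36 to 44.1 and 5.00 to 38.7, so replicate 1 sets the low end. The score difference between X and autosomes was 0.12 between means of bin medians, another measure than the main difference of medians (permutation p = 0.81). As a difference of medians on another scale, it was 0.85 per kb of width (permutation p = 0.091). Neither passed the threshold. Single replicate lists gave 3.64 to 56.5 on their own scales. Whole-series peaks found in both replicates were 11.8% when 50% of the peak had to be covered. With 50% reciprocal overlap, shared peaks were 23.0% of replicate 1 and 14.4% of replicate 2, and the X excess of shared replicate 1 peaks was 20.1 points. Arm to centre ratios on autosomes were 0.72 to 1.41 in single replicate lists. On X they gave 1.00 to 1.08, a centre of 50% of the length gave 0.99, and the upper 50% of peaks by score gave 1.10 (permutation p = 0.038). Single lists gave 0.79 to 1.91 on I, 0.83 to 2.07 on II, 0.72 to 1.29 on III, 0.71 to 1.19 on IV and 0.59 to 1.10 on V. The ratio also changed direction on I with a centre of 50% (0.86), and on IV with 250-kb bins (0.996) and with the upper 50% of peaks (0.74). Spacing relative to random placement was 0.86 to 0.98 on X and 0.69 to 1.02 on autosomes in single lists, and 1.14 and 0.94 with peaks closer than 500 bp merged, against 1.04 and 0.77 as deposited. A rise with merging is built in, because random placement was not merged. The X share in single lists was 59.4 to 95.9% in the highest 20% and 52.8 to 85.2% in the lowest, with 1889 to 4743 X peaks and 501 to 1384 autosomal peaks. Where a ratio moved, the cause was not tested. In all, 71 alternatives kept direction and call or, for 3 peak numbers with no test (6601 X and 1465 autosomal peaks after merging, 1384 autosomal peaks in replicate 1), stayed near the main value. Another 14 changed direction and were counted as such whatever their p. Of the rest, 6 kept direction and went above an unadjusted p of 0.05, 5 kept it and went below, and 8 moved a value that has no test. For arms of single chromosomes this count uses unadjusted p, so the 3 on III that kept direction and went above 0.05 lost no call that had passed adjustment. Replicate 1 alone also went above it on III (permutation p = 0.26) and is counted among the changes of direction. The alternatives of spacing, of X share by score, of peak number and of chromosome size were chosen after seeing the data. Alternatives for gene position, gene classes and motif were not run, as no annotation or sequence of the build was used here. No paired analysis was possible because the input samples have no list here, so no groups with shared replicate numbers could be compared. Depth is unknown, so whether more reads in a sample would fill the gaps between lists could not be assessed.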

Other observations

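Of the tests of scores around the strongest X peaks, those of the whole-series list and of replicate 2 sites with replicate 1 scores were set before their results were seen; all other values here were chosen after the data were seen.

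A set of regions was marked by very wide peaks. Close to the last peak end of chromosome I, which was taken as its size, a wide peak was present in all 3 lists, at I 15060233 to 15071363 in the whole-series list (11.1 kb), with a score of 3100 in both replicate lists. In the gene order of assembly WBcel235, 4 of the last 10 genes of chromosome I are ribosomal RNA genes. The widest peak of the whole-series list, X 4032523 to 4056468 (23.9 kb, score 36.47), was matched in replicate 1 by X 4031318 to 4056494 (25.2 kb, score 890) and overlapped no peak of replicate 2. Of the 8 autosomal peaks over 5 kb in replicate 2, 8 overlapped a replicate 1 peak, and 15 of its 18 such X peaks did. In replicate 1, 4 of 9 autosomal peaks over 5 kb overlapped a replicate 2 peak, and the 1 such X peak did not. All 6 left chromosome ends had a peak within 1 kb in each of the 3 lists. A peak within 10 kb of the right end was present on 6 chromosomes in the whole-series list, 4 in replicate 1 and 3 in replicate 2. Because the last peak end of any list was taken as the chromosome size, at least 1 list had to reach each right end.

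The first 500 kb of X was the least dense of the 35 X bins in all 3 lists, at 64.4% of the median bin in the whole-series list, 66.7% in replicate 1 and 49.3% in replicate 2. The last bin of X had 480 peaks per Mb in the whole-series list, against a median of 522.

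The 100 highest scoring X peaks of the whole-series list, which scored at least 119.51, were a median of 110 kb apart. The hypothesis that other X peaks score higher near these sites was not borne out. Within 10 kb the median score of other X peaks was 6.76, and farther away it was 6.80, a difference of -0.04 that lay within the range of 1000 circular shifts (-0.55 to 0.55). Without peaks within 2 kb the difference was 0.02, and with sites from replicate 2 and scores from replicate 1 it was -12.74 on that list's scale (shift range -13.9 to 18.1). With sites from replicate 1 and scores from replicate 2 it was 17.4 (shift range -20.6 to 22.4), and with both from replicate 2 it was 3.37 (-21.5 to 21.98). With no difference to explain, splitting of broad peaks and noise of a single library could not be weighed by these values. The distance of 10 kb and the use of scores rather than read signal limit this test, and a gradient in read signal between peaks was not measured.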
